A study of Mus musculus with 6 samples.

How the data were processed

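RNA from hearts of 3 WT mice and 3 mice labelled as ERRα-null was hybridised to Affymetrix Mouse430_2 arrays, a chip type named in the one array header used here. Per the labels, all 6 mice were male, and 5 were C57BL/6J aged 2 to 3 months; the labels of WT 1 give no strain, age or tissue entry, although its source is given as heart, and a comment in the header of its array numbers it as another WT mouse than its title does. The title was used. RNA was extracted with a fibrous tissue kit and labelled with biotin, per the labels' protocols. The deposited values are signal intensity per probe set on a linear scale from MAS5, per the submitters' processing notes, which combine the probe pairs of each probe set into one value. They are linear and not centred, and run from 0 to 10889.5. The scaling target and the detection calls are not given in the sources used here, so a dim signal could not be told from background. Column medians of the deposited intensity were 16, 13.2 and 12.4 for WT 1 to 3 and 13.7, 13.5 and 13.4 for KO 1 to 3, and means trimmed by 2% were 72.1, 57.3, 57.1, 60.7, 58.6 and 63.4, so the arrays were not on a common level, with WT 1 the brightest. The design fixed before the data were examined took the values to be scaled per array already; it was kept, with no further normalization, and quantile normalization, median centring and cyclic loess were run beside it. The median log2 difference of all genes was -0.028.

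Of the 45099 probe sets 62 are controls, 34958 have 1 gene symbol in the platform table, 932 have several and 9160 have none; probe sets with several or none were left unnamed. By gene identifier 34754 matched the GRCm38 gene table, and 0 symbols changed. Log2(signal + 16) was used, on which a fold change understates the change of dim genes. A probe set was kept when its mean over the 6 arrays reached the 40th percentile of the non-control probe sets (log2 4.59, a signal of 8.17), and each gene was read from its brightest probe set, which left 12946 genes. Groups were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Esrra was tested over all non-control probe sets without the filter, as designed, and its value in the filtered fit is given beside that. The labels number mice within each genotype and do not say that equal numbers pair. No pair of arrays held identical values. The p-values rest on the spread between these hearts, with each gene's variance drawn strongly toward that of genes of like intensity. In the main fit the shared variance carried 45.6 prior degrees of freedom, so the p-value of a gene depends little on its own spread. In the gene comparison without KO 1 the SE was 0.206 for Car3, Adipoq and Cyp2e1 alike. For the same genes it was 0.384 with the atrial score as a covariate and 0.378 to 0.379 with the adipocyte score. The p-values of those fits rested almost wholly on the shared variance, so a smaller one is not stronger evidence.

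The 34 gene lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, which asks whether a list's genes move one way on balance and does not compare it with other genes. They were fatty acid oxidation, complex I subunits, complexes II to IV and cytochrome c, ATP synthase, TCA cycle and pyruvate dehydrogenase, glycolysis and glucose use, PPAR alpha responsive genes, ketone and branched chain amino acid use, creatine and ATP transfer, lipid storage and synthesis, calcium handling, sarcomere, hypertrophy and fetal program, ion channels, pumps and connexins, nuclear receptors and coregulators, mitochondrial ribosome, mitochondrial import and chaperones, cytosolic ribosome, antioxidant and stress defence, extracellular matrix, angiogenesis and hypoxia, interferon response, circadian clock, immediate early genes, and markers of fibroblasts, endothelium, smooth muscle and pericytes, leukocytes, erythroid and blood cells, adipocytes, atrial myocytes, skeletal muscle, neural and Schwann cells, and of lung, thymus and cartilage. Genes near Esrra were taken from gene order in the same gene table, 100 tested genes on each side, and compared by Fisher's exact test.

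Genes were named by a rule fixed before the data were examined: Esrra, Esrrb, Esrrg, Ppargc1a, Ppargc1b, Ppara, Nnt, Xist and Ddx3y, the last of which was not among the tested genes; the 10 largest rises and 10 largest falls among genes past the threshold with separated groups, skipping clone and predicted names; up to 4 members of smallest p in each list; and the 6 genes of smallest p near Esrra. The 5 atrial and 4 adipocyte markers behind the scores were chosen after the values were seen. Alternatives were other pseudocounts, scalings, filters, rules for probe sets (among them leaving out shared-probe sets, those whose suffix marks probes shared between transcripts), variance models, array weights, a replicate block and leaving out each heart. Added after seeing the data were quantile normalization without the library labelled KO 1, the atrial score and the adipocyte (fat) score as covariates, and Esrra in the filtered fit. On data simulated for this comparison over 12946 genes, log2 changes of 0.5, 1 and 2 were recovered at 19.7, 91.6 and 100%, and 5.12% of calls were false. The simulated noise was independent between genes and drawn from the fitted variance model, without differences in array level or tissue content. These figures therefore check the procedure and do not give the share of false calls in the real data.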

Results

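Transcript levels were measured in the hearts of 6 male mice kept under basal conditions. The labels give 3 hearts as wild-type (WT) and 3 as null for estrogen-related receptor alpha (ERRα), an orphan nuclear receptor encoded by Esrra that controls genes of mitochondrial energy metabolism. Each heart was hybridised to its own Affymetrix Mouse430_2 array, and 45099 probe sets were read per array. The values were not on a common level across arrays. The median signal per array was 16, 13.2 and 12.4 in WT 1 to 3 and 13.7, 13.5 and 13.4 in the libraries labelled KO 1 to 3. Pearson correlations across genes, which are not independent replicates, lay between 0.9845 and 0.9849 within WT, between 0.979 and 0.983 within the libraries labelled KO, and between 0.969 and 0.981 across the groups. The first principal component held 36.5% of the variance. WT 1 to 3 lay at -21.6, -13.99 and -9.9 on it, and KO 1 to 3 at 3.67, 19.1 and 22.7. The number of arrays limits the precision of every comparison.

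Esrra, the targeted gene, was measured first, as a check of the labels. Its brighter probe set gave signals of 368.1, 394.4 and 349.1 in the WT hearts, and 24 and 18 in the libraries labelled KO 2 and KO 3. The library labelled KO 1 gave 180.1, which is 48.6% of the WT mean, against 6.48% for KO 2 and 4.86% for KO 3. The signal in KO 1 therefore goes against its label, and every direction given below for the libraries labelled KO is drawn with that library included unless its omission is stated. The log2 difference was -2.58 (SE 0.475, 3 against 3 hearts), with an adjusted p of 0.0678 in limma over all probe sets without a filter, the fit set for this gene before the data were examined. It did not pass the threshold of 0.05 in that fit. In the filtered fit of the gene comparison the same difference had an SE of 0.283 and an adjusted p of 3.8e-09. Without the library labelled KO 1 the unfiltered difference was -3.39, with an adjusted p of 4.25e-06. The dimmer probe set gave 11.5, 8.3 and 9.1 in WT and 8.3, 0.5 and 1.3 in KO 1 to 3 (log2 difference -0.42, SE 0.180, adjusted p = 0.572). Where either probe set lies relative to the deleted part of the gene is not given in the sources used here.

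The comparison of ERRα-null with WT hearts asked which transcripts depend on the receptor in the unstressed heart. The uncoupling protein gene Ucp3 and 6 of 24 fatty acid oxidation genes fell in the libraries labelled KO, while the coactivator gene Ppargc1a, 8 of 20 genes of hypertrophy and the fetal program, 8 of 17 atrial markers and 6 of 11 adipocyte markers rose. As lists these groups did not pass with an estimated correlation (adjusted p = 0.592 with an estimated correlation for fatty acid oxidation, 0.328 for hypertrophy and the fetal program, and 0.326 for both sets of markers). With quantile normalization the counts were 10 of 24, 6 of 20, 8 of 17 and 2 of 11. Ppargc1a, which encodes PGC-1α, a coactivator of ERRα and other regulators of mitochondrial genes, rose from a signal of 539 ± 64.8 to 1124 ± 157 (SD, n = 3 each), a log2 difference of 1.03 (SE 0.148, limma adjusted p = 2.34e-06). With the adipocyte score as a covariate Ppargc1a was at 0.75 (SE 0.331) and did not pass, in a fit where Esrra itself was at 0.22. With the atrial score it was at 1.26 (limma adjusted p = 0.0436). Ucp3, a mitochondrial carrier of muscle, fell from 235 ± 50.1 to 63.6 ± 26.3, and Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 180 ± 43.6 to 46.6 ± 19.6. The largest rise among genes with separated groups was that of Car3, a carbonic anhydrase abundant in fat and muscle, from 46.8 ± 19.4 to 905 ± 587.

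Of 12946 genes tested, 231 were higher and 153 lower in the libraries labelled KO at an adjusted p under 0.05 (limma on log2 of signal plus 16, two-sided, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 1620. All 3 libraries labelled KO lay beyond all 3 WT hearts for 209 of the higher and 141 of the lower genes. Over all genes tested, the groups did not overlap for 16.2%, against 10% by chance. At least 1.5-fold differences were found for 213 higher and 135 lower genes, and at least 2-fold differences for 60 and 19. The counts depended on single hearts. They were 103 higher and 19 lower without WT 1, which a comment in its array header numbers as another WT mouse than its title does, 173 and 84 without KO 2, and 119 and 77 without KO 3. Without the library labelled KO 1, whose Esrra signal goes against its label, they were 299 and 209, and 334 of the 384 genes were shared. The p-values of that fit rested almost wholly on variance shared between genes, so its larger counts are not stronger evidence. With no filter on dim probe sets they were 48 and 18, and with no intensity trend in the variance 114 and 57.

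The 10 genes with the largest rise among those with separated groups were Car3 (log2 difference 3.59), Ppp1r1b (2.65), Adipoq (2.64), Nr4a3 (2.45), Cyp2e1 (2.44), Sln (2.28), Scd1 (2.09), Dkk3 (2.03), Mybphl (1.88) and Jchain (1.83). Their adjusted p ran from 4.95e-13 for Car3 to 8.05e-07 for Jchain. Nr4a3, an orphan nuclear receptor, gave 2, 3.4 and 5 in WT and 53.4, 124.6 and 105.8 in KO 1 to 3, although its other probe sets had log2 differences of 0.64 and -0.16. Dkk3, a secreted protein of the Dickkopf family, rose from 87.6 ± 38.9 to 389 ± 41.2. With the atrial score as a covariate Dkk3 was at 0.93 (limma adjusted p = 0.6), and with the adipocyte score at 2.09 (3.39e-05). Ppp1r1b was at 0.17 and Cyp2e1 at 0.55 with the adipocyte score, against 2.88 and 2.84 with the atrial score. Adipoq encodes the adipocyte hormone adiponectin. Its signal was 54 in KO 1, 390.7 in KO 2 and 323 in KO 3, against 15.7 to 22.3 in WT.

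The 10 genes with the largest fall in the same fit were Esrra itself (-2.58), Lrtm1 (-1.89), Myot (-1.84), Prune2 (-1.77), Scn4b (-1.75), Ucp3 (-1.68), Angptl4 (-1.66), Rasl10b (-1.38), Igsf1 (-1.19) and Rap1gap2 (-1.17). Their adjusted p ran from 1.76e-09 for Lrtm1 to 4.71e-05 for Rap1gap2. Myot, which encodes the Z-disc protein myotilin, gave 355.1, 335.8 and 360.4 in WT and 215.2, 59.2 and 45.6 in KO 1 to 3. Scn4b, a β subunit of the cardiac sodium channel, fell from 110 ± 24.5 to 22.7 ± 15.3 (SD, n = 3).

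**Figure D1:**
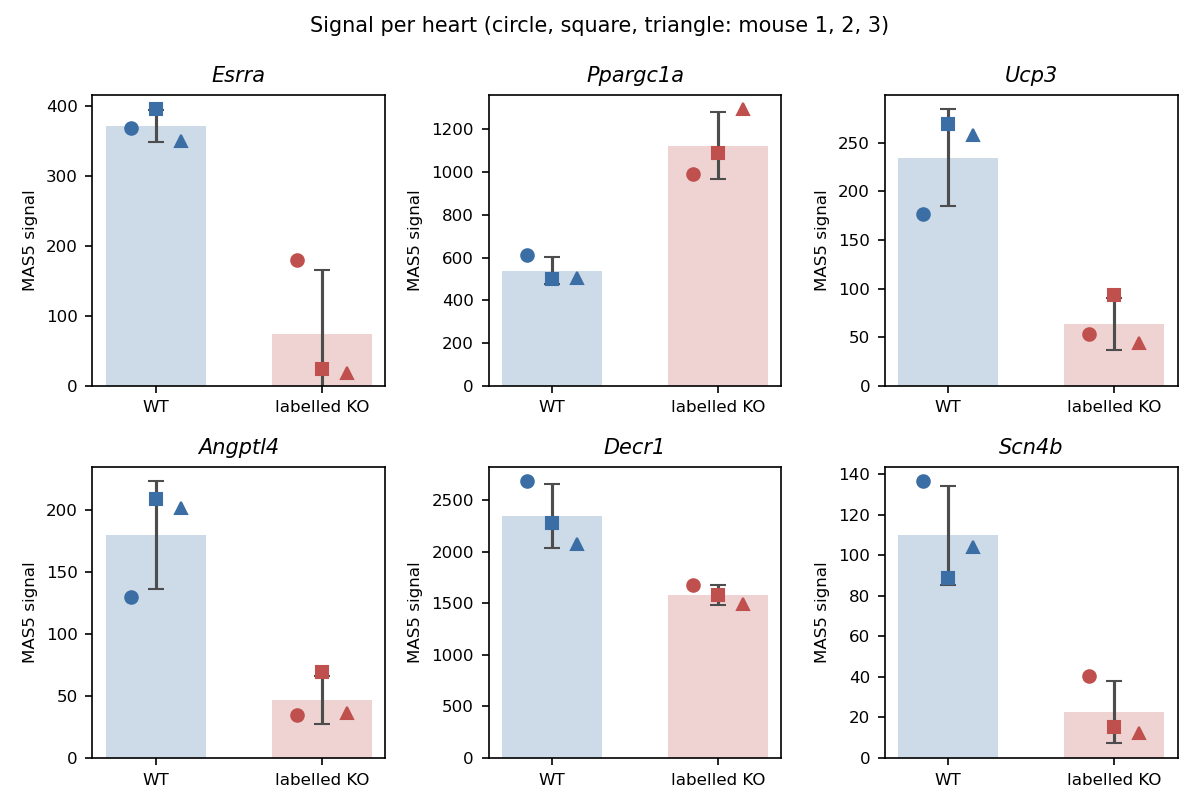
MAS5 signal (linear axis from 0) of 6 genes in each of the 6 hearts, with bars for the group mean, error bars for the SD and 3 points per group. For Esrra the library labelled KO 1 (circle, 180.1) lies between the WT hearts (349.1 to 394.4) and the libraries labelled KO 2 and KO 3 (24 and 18).

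Esrrb, Esrrg, Ppargc1b and Ppara, related receptors and a coactivator, did not pass the test. The log2 difference was -0.18 (SE 0.178) for Esrrb, 0.11 (SE 0.169) for Esrrg, -0.20 (SE 0.153) for Ppargc1b and 0.15 (SE 0.171) for Ppara, with adjusted p between 0.676 and 0.870. Esrrg was at -0.10 as the mean of its probe sets, and Ppara at -0.25 without KO 1. Nnt, which is partly deleted in the labelled strain C57BL/6J, gave 4255 ± 625 in WT and 3438 ± 856 in the libraries labelled KO (log2 difference -0.32, adjusted p = 0.2); without KO 1 it passed (-0.52, adjusted p = 0.00515). Another bright Nnt probe set gave 1001 to 1790.6 over the 6 hearts (log2 difference -0.25). Where these probe sets lie relative to the deletion is not given in the sources used here, so the signals do not check the strain label. Xist, transcribed from the inactive X chromosome, stayed at 15.6 or less in every heart, all of them labelled male.

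Some markers of atrial myocytes and of fat differed between the groups. Over 5 atrial myocyte markers (Sln, Myl4, Myl7, Mybphl and Bmp10) the mean log2 signal relative to WT was -0.31, -0.64 and 0.95 in WT 1 to 3 and 2.11, 1.85 and 1.53 in KO 1 to 3. Over 4 adipocyte markers (Adipoq, Car3, Cidec and Retn) it was 0.049, -0.075 and 0.026 in WT and 0.877, 2.65 and 2.4 in KO 1 to 3. With the adipocyte score as a covariate, an alternative chosen after seeing the data, 15 genes were higher and 11 lower, and with the atrial score 60 and 14. Both scores were higher in every library labelled KO than in every WT heart, so these fits also take out part of the difference by genotype. With the adipocyte score Esrra itself was at 0.22. A loss under either score therefore cannot tell tissue content from genotype. The markers that make up a score shrink under it by construction.

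**Figure D2:**
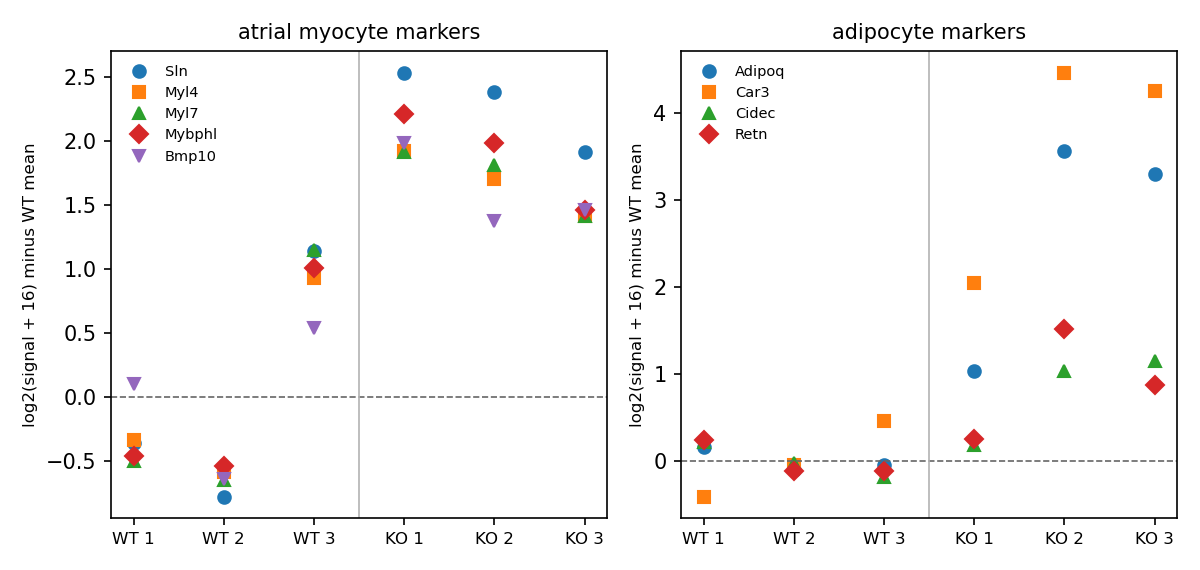
Log2(signal + 16) of atrial myocyte markers (left) and adipocyte markers (right) in each heart, relative to the WT mean of each gene, with 1 symbol shape and colour per gene. WT 3 lies above the other WT hearts for the atrial markers (mean 0.95), and KO 1 lies below KO 2 and KO 3 for the adipocyte markers (0.877 against 2.65 and 2.4).

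Of 34 gene lists fixed before the data were examined, 15 stood apart from the other genes by camera with a preset correlation of 0.01, with 9 higher and 6 lower in the libraries labelled KO. With an estimated correlation 0 of the 34 lists did, and by fry 1 did. The fry result depended on the setting. With quantile normalization PPAR alpha responsive genes, mitochondrial import and chaperones, antioxidant and stress defence and fibroblast markers passed (fry adjusted p = 0.0398 each). Without KO 1 the lowest fry adjusted p was 0.0503. How many members passed depended on the scaling of the arrays. With quantile normalization 10 fatty acid oxidation genes fell against 6 in the main fit, 9 fibroblast markers rose against 3, 6 matrix genes rose against 4, 4 mitochondrial ribosome genes fell against 2, 3 mitochondrial import genes fell against 1, and 3 glycolysis genes fell against 0, while 2 adipocyte markers rose against 6, 0 smooth muscle and pericyte markers against 2, 6 hypertrophy and fetal genes against 8, and 0 lipid storage genes against 3. Of the genes named as past the test here and near Esrra, Scd1, Retn, Acot1, Hrc, Myh7, Kcne1, Gsta4, Eln, Ccn1, Acta2, Cnn1, Ppbp, Tnni2, Mbp, Scgb1a1, Comp, Tbc1d10c and Slc29a2 did not pass with quantile normalization (adjusted p from 0.0511 to 0.269), and Nrip1, Nr1d1, Timp3, Cnn1 and Comp did not without KO 1. Fatty acid oxidation was called lower (median -0.27, adjusted p = 6.2e-10, and adjusted p = 0.592 with an estimated correlation). Of 24 members tested, 6 fell, 0 rose and 18 did not pass the test, and 14 were lower adjusted over the list alone. Decr1, the dienoyl-CoA reductase needed for unsaturated fatty acids, fell from 2348 ± 314 to 1584 ± 94.9, and Slc25a20, the mitochondrial carnitine carrier, from 1181 ± 80.7 to 789 ± 103 (SD, n = 3). Hadha (log2 difference -0.48) and Acad11 (-0.65) fell too. With the adipocyte score as a covariate, under which Esrra itself was at 0.22, the list's call was lost (median -0.099, adjusted p = 0.692). Decr1 was then at -0.42, Slc25a20 at -0.22, Hadha at -0.11 and Acad11 at 0.025, and none of them passed. The PPAR alpha responsive genes had the lowest median, -0.51 over 13 members. Ucp3, Angptl4, Txnip (-0.84) and Acot1 (-0.94) were among 6 that fell, 0 rose and 7 did not pass, and 12 were lower adjusted over the list alone. The list's adjusted p was 1.82e-16 by camera and 0.0205 by fry, and adjusted p = 0.0523 with an estimated correlation. In the same order these were 7.07e-10, 0.0398 and 0.371 with quantile normalization, and 5.11e-16, 0.0503 and 0.071 without KO 1.

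Of the respiratory chain, complex I subunits were called lower without any single member passing the test in the main fit. Of 34 subunits 33 had negative differences, with a median of -0.16 and an adjusted p of 2.76e-06 (adjusted p = 0.864 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. With quantile normalization Ndufv3 passed (adjusted p = 0.0483) and 7 were lower adjusted over the list alone. The call was lost with the adipocyte score as a covariate (median -0.036, adjusted p = 0.692). Ndufv3 was at -0.28 (SE 0.101) and Ndufb7 at -0.32 (SE 0.122). The complexes II to IV with cytochrome c (median -0.068, adjusted p = 0.144), ATP synthase (-0.078, 0.164) and the TCA cycle with pyruvate dehydrogenase (-0.071, 0.202) were not called, and 0 of their 26, 16 and 22 members passed on either count. Cox7a1 was at -0.22 (SE 0.109), Atp5g1 at -0.17 (SE 0.10) and Pdha1 at -0.17 (SE 0.110). In the other direction lay Cox7c (0.55, SE 0.225), which had the smallest p of its list, and Idh3a (0.16, SE 0.112). Cox7c was read from a shared-probe set with a signal of 22 or less in every heart. Ketone and branched chain amino acid genes were called lower (median -0.18, adjusted p = 0.00246, and adjusted p = 0.902 with an estimated correlation) with 0 of 20 members past the test on either count. Dbt was at -0.43 (SE 0.167). The call was lost without KO 3, and the median was 0.011 with the adipocyte score as a covariate. Of 76 mitochondrial ribosome genes 2 fell, Mrpl55 (-0.72) and Mrpl34 (-0.68), on either count, and 66 were negative (median -0.17, adjusted p = 4.76e-05, and adjusted p = 0.902 with an estimated correlation). Of 35 mitochondrial import and chaperone genes 1 fell, Timm29 (-0.65), on either count (median -0.12, adjusted p = 0.0308, and adjusted p = 0.902 with an estimated correlation), and the call was lost in 8 of 24 settings. Creatine and ATP transfer genes were not called (median -0.075, adjusted p = 0.293) and 0 of 16 passed, with Gamt at -0.37 (SE 0.197). The cytosolic ribosome was not called (median -0.034, adjusted p = 0.373), 0 of 44 members passed, and its direction turned with quantile normalization (median 0.022) and cyclic loess (0.026).

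Glycolysis and glucose use held 3 members that rose of 24, Pfkp (0.84), Hk1 (0.71) and Pgam1 (0.64), with 3 higher and 3 lower adjusted over the list alone. The list was not called (adjusted p = 0.974), and its median of -0.055 and its test differed in sign. With the adipocyte score as a covariate Hk1 was at -0.019, Pfkp at -0.20 and Pgam1 at 0.40, and none of them passed. In lipid storage and synthesis 3 of 21 rose and 4 fell, the same counts as adjusted over the list alone. Gpam, the first enzyme of glycerolipid synthesis, fell from 1345 ± 113 to 761 ± 157, Dgat2, which makes triglyceride, from 1170 ± 201 to 669 ± 94.0, and Vldlr, the very low density lipoprotein receptor, by 0.62 on the log2 scale, while Scd1 rose. The list was not called (median -0.095, adjusted p = 0.474). The nuclear receptors and coregulators were not called (median -0.039, adjusted p = 0.708). Of 30 members 1 rose, Ppargc1a, and 2 fell, Nrip1 (-0.61) and Nr1d1 (-0.58), with 1 higher and 3 lower adjusted over the list alone. In the circadian clock list Dbp (-0.87) and Nr1d1 fell of 18 members, with 2 higher and 2 lower adjusted over the list alone (median -0.023, adjusted p = 0.645).

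Genes of hypertrophy and the fetal program were called higher. Of 20 members 8 rose, 1 fell and 11 did not pass, with 9 higher and 1 lower adjusted over the list alone (median 0.28, adjusted p = 1.2e-08, and adjusted p = 0.328 with an estimated correlation). Nppa, the atrial natriuretic peptide gene, rose from 2951 ± 1890 to 7147 ± 267, Ccn2, a matrix-associated growth factor, from 252 ± 14.5 to 720 ± 102, and Lgals3, galectin-3, from 44.5 ± 21.0 to 155 ± 22.8 (SD, n = 3). The call held in all 24 settings, with medians from -0.0044 (every probe set) to 0.42. With the atrial score as a covariate Nppa, which belongs to the atrial list too, was at -0.21, Lgals3 at 0.74 (adjusted p = 0.927) and Ccn2 at 1.28 (SE 0.366 against 0.157 without it, adjusted p = 0.0693). Acta1, the skeletal α-actin also used in the fetal heart, fell by 0.71. In the sarcomere list Tnni1 (1.44) and Myh7 (0.78) rose and Tcap (-0.61) and Acta1 fell of 27 members, with 2 higher and 4 lower adjusted over the list alone (median -0.063, adjusted p = 0.293). In calcium handling Sln, sarcolipin, rose from 492 ± 377 to 2088 ± 444. With the atrial score as a covariate Sln was at 0.10 and did not pass, but Sln is part of that score, so this follows by construction. Cacna1g, a T-type channel, rose too (0.71) and Hrc fell (-0.63) of 25 members, with 2 higher and 2 lower adjusted over the list alone (median -0.067, adjusted p = 0.474). Of 24 ion channels, pumps and connexins 2 rose, Kcne1 (1.30) and Kcna5 (0.74), and Scn4b fell, with 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.974). The median of -0.039 and the test differed in sign.

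**Figure D3:**
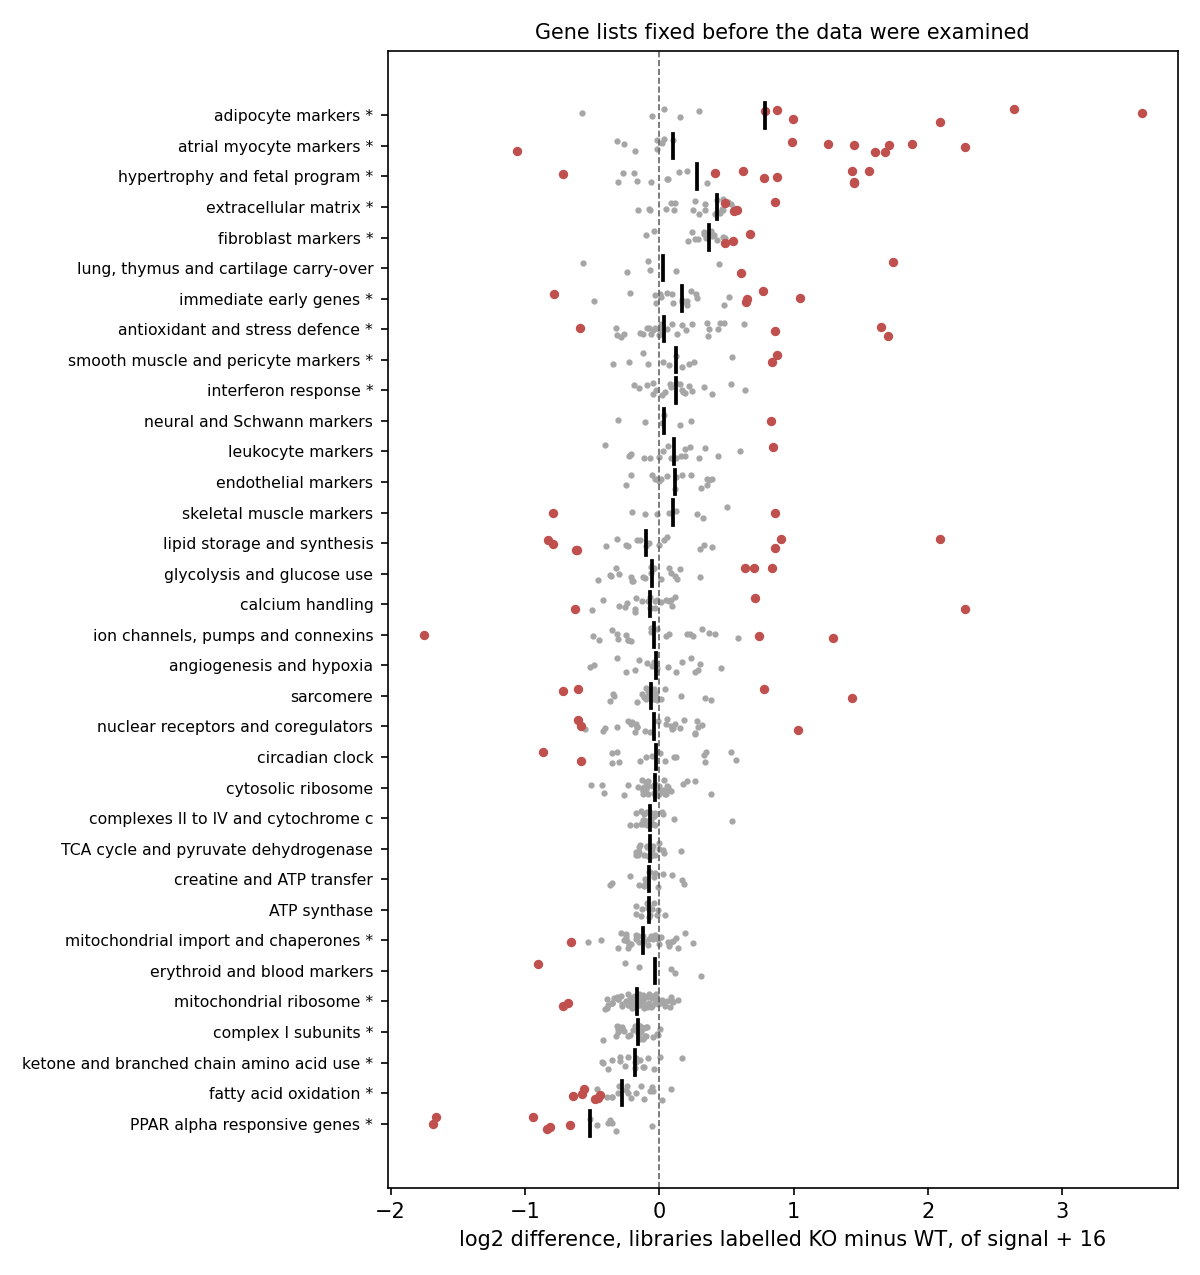
Log2 difference (libraries labelled KO minus WT, of signal + 16) of every member of the 34 gene lists, with a bar at each list's median, larger red points for members past an adjusted p of 0.05, and an asterisk for the 15 lists called by camera with a preset correlation. Adipocyte markers reach a median of 0.79 and PPAR alpha responsive genes -0.51.

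Extracellular matrix genes were called higher. Of 28 members 4 rose, Eln (0.86), Timp2 (0.58), Timp3 (0.55) and Col3a1 (0.49), and 15 were higher adjusted over the list alone (median 0.43, adjusted p = 2.26e-11, and adjusted p = 0.592 with an estimated correlation). With the adipocyte score as a covariate the median was -0.0057 (adjusted p = 0.901). Fibroblast markers shared 5 members with other lists, and 3 of 18 rose, Vim (0.55), Mfap5 (0.67) and Col3a1, with 12 higher adjusted over the list alone (median 0.37, adjusted p = 4.09e-10, and adjusted p = 0.425 with an estimated correlation). With quantile normalization 9 rose and 15 were higher adjusted over the list alone. In antioxidant and stress defence Hspa1b and Hspa1a, the inducible Hsp70 genes, whose sequences are nearly identical, rose by 1.71 and 1.65, Gpx3 rose by 0.86 and Gsta4 fell by 0.59 of 32 members, with 7 higher and 2 lower adjusted over the list alone (median 0.035, adjusted p = 0.00145, and adjusted p = 0.864 with an estimated correlation), and the call was lost with the atrial score as a covariate (adjusted p = 0.0819). Under that covariate Gpx3 was at 0.25 and did not pass, Hspa1a was at 1.40 (limma adjusted p = 0.0587) and Hspa1b at 1.54 (0.0155). Of 23 immediate early genes 4 rose, among them Cdkn1a (1.05), Klf4 (0.78) and Klf2 (0.66), and Ccn1 fell (-0.78), with 6 higher and 2 lower adjusted over the list alone (median 0.17, adjusted p = 0.00215, and adjusted p = 0.58 with an estimated correlation). That call was lost with array weights, without WT 1, and with the atrial score as a covariate, where the median stayed positive (0.0059) and the direction relative to the other genes turned (adjusted p = 0.839). The interferon response was called higher with 0 of 21 members past the test on either count (median 0.13, adjusted p = 0.0441, and adjusted p = 0.902 with an estimated correlation). Igtp was at 0.64 (SE 0.218), and passed without KO 1 (1.03, adjusted p = 5.8e-05), the call held in 13 of 24 settings, and the list turned without KO 3 (median -0.066, adjusted p = 0.535) and with the adipocyte score as a covariate (median -0.47, adjusted p = 8.77e-06, and adjusted p = 0.982 with an estimated correlation). Angiogenesis and hypoxia genes were not called (median -0.026, adjusted p = 0.974), 0 of 18 passed, and the direction turned with cyclic loess (median 0.016). Hif1a was at -0.49 (SE 0.165) and passed with quantile normalization (adjusted p = 0.0495).

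Atrial myocyte markers, of which 5 are in other lists, were called higher, with 8 of 17 members that rose, 1 that fell and 8 that did not pass, and the same 8 and 1 adjusted over the list alone. Sln, Myl4 (1.68), Nppa and Mybphl led it (median 0.10, adjusted p = 6.22e-12, and adjusted p = 0.326 with an estimated correlation). With quantile normalization 8 of its members rose and 0 fell over all genes, with 8 higher and 2 lower adjusted over the list alone. Adipocyte markers had the highest median, 0.79, with 6 of 11 that rose and 5 that did not pass, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 3.44e-10, and adjusted p = 0.326 with an estimated correlation). With quantile normalization 2 of 11 rose. Car3, Adipoq, Scd1 and Retn (0.88) led it, and 3 of its members are in other lists. Smooth muscle and pericyte markers were called higher, with Acta2 (0.87) and Cnn1 (0.84) as 2 of 13 that rose and 3 higher adjusted over the list alone (median 0.12, adjusted p = 0.0379, and adjusted p = 0.592 with an estimated correlation), and the call was lost in 12 of 24 settings. Not called were endothelial markers (median 0.12, adjusted p = 0.072, 0 of 17 past the test, Robo4 at 0.39 with SE 0.171, but called with quantile normalization at a median of 0.14 and an adjusted p of 0.0122, with 1 member that rose and 3 higher adjusted over the list alone, and adjusted p = 0.41 with an estimated correlation), leukocyte markers (0.11, 0.0701) and erythroid and blood markers (-0.031, 0.474). Cd163, a macrophage receptor, was the 1 of 20 leukocyte markers that rose (0.85), with 2 higher adjusted over the list alone, and that list was called without KO 1 (median 0.30, adjusted p = 3.84e-05, and adjusted p = 0.824 with an estimated correlation). Ppbp, a platelet gene, was the 1 of 6 blood markers that fell (-0.90), on either count. The blood list was called lower with the atrial score as a covariate (median -0.44, camera adjusted p = 1.17e-05) and with the adipocyte score (-0.54, 0.00161). With an estimated correlation it was not called in either fit (camera adjusted p = 0.728 and 0.982). Skeletal muscle markers (0.099, 0.49) held Tnnt1 that fell (-0.79) and Tnni2 that rose (0.86) of 10, neural and Schwann markers (0.034, 0.335) held Mbp that rose (0.84) of 7, and lung, thymus and cartilage genes (0.027, 0.188) held Scgb1a1 and Comp (0.61) that rose of 8, each with the same counts adjusted over the list alone. Without KO 1 the lung, thymus and cartilage list was called higher (median 0.058, camera adjusted p = 0.0183, and 0.485 with an estimated correlation). Of its 8 members 4 were then positive and 4 negative, and only Scgb1a1 (2.62) passed. Scgb1a1, a secretory protein of the airway, had a signal of 323.5 in KO 2, 23.2 in KO 3 and 4.2 or less in the other hearts. Although they passed the test, Acta2, Cnn1, Ppbp, Tnni2, Mbp and Scgb1a1 had groups that overlapped. Tnni2 gave 37, 12.3 and 2.6 in WT and 22.2, 42.3 and 58.6 in KO 1 to 3.

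Genes close to Esrra on its chromosome were compared with the rest, since a null allele can carry flanking sequence of another strain. Among the 100 tested genes on each side, 5 of 200 passed an adjusted p of 0.05, against 378 of 12691 elsewhere (odds ratio 0.835, Fisher's exact test, two-sided p = 1). At an unadjusted p under 0.05 it was 23 against 1595 (odds ratio 0.904, Fisher's exact p = 0.747). The 5 were Rom1 (log2 difference -0.93), Scgb1a1, Neat1 (-0.66), Tbc1d10c (0.73) and Slc29a2 (0.68), while Trmt112, the tested gene next to Esrra, was at 0.51 (SE 0.156, adjusted p = 0.0595; 0.00902 with quantile normalization). The odds ratio was 1.45 with 200 genes on each side, of which 109 were available below Esrra (Fisher's exact p = 0.231).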

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

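The tests of each WT heart left out in turn, of the genes by direction and of all members of the marker lists were chosen after the result was seen. Probe sets outside the gene comparison, 3864 with no single gene name, held signals that differed between the groups, with 31 higher and 19 lower in the libraries labelled KO at an adjusted p under 0.05 (limma). The smallest adjusted p, 1.07e-10, belonged to a probe set with 22.1, 21.7 and 20.1 in WT and 120.5, 404.8 and 392.4 in KO 1 to 3.

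The library labelled KO 1 had an Esrra signal between WT and the other libraries labelled KO. On 508 genes called without it, on a scale from 0 at the WT mean to 1 at the mean of KO 2 and KO 3, its median position was 0.459 (95% bootstrap interval over genes 0.407 to 0.5). KO 2 and KO 3 left out in turn lay at 0.915 and 1.08, on their own sets of 259 and 200 genes. Their scales end at a mean that includes KO 1, so these positions do not compare directly with 0.459. A WT heart under a wrong label had been given a bound of under 0.25 beforehand, and its absence a position above 0.5; the value met neither, so that test alone left it open. When each WT heart was left out instead, the highest of their positions was 0.196 (0.146 to 0.232), and KO 1 lay at 0.452 to 0.48 on the same genes, with intervals above those of all 3 WT hearts, which argues against it. The intervals resample genes of single libraries and do not measure the spread between libraries. Over all tested genes the array closest to KO 1 was WT 3 (r = 0.9808), against 0.9807 for KO 2 and 0.9786 for KO 3. With WT 1 and WT 2 it correlated at 0.9792 and 0.9800, while WT hearts reached at least 0.9845 among themselves. A mixture of WT and KO RNA in about equal parts stays open. The median position of KO 1 differed from that of Esrra itself (0.545) by -0.085, inside the 0.15 set beforehand. The genes higher in KO 2 and KO 3 lay at 0.363 (0.309 to 0.428) and the genes lower in them at 0.522 (0.485 to 0.574). A mixture would place both alike. That gap of -0.16 does not decide it, since the gap was -0.151 for KO 2 left out, and -0.066 for KO 1 with quantile normalization. The signals of Sln, Myl4, Myl7 and Mybphl in KO 1 were above those in KO 2 and KO 3. Nppa in KO 1 (7169.9) lay between KO 2 (6869) and KO 3 (7401.3). Atrial content that differed between samples could give such values in a mixture too, so they do not decide it either. A heterozygous animal stays open and was not tested.

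Atrial myocyte markers were called higher in the libraries labelled KO (adjusted p = 6.22e-12, and adjusted p = 0.326 with an estimated correlation), with 8 of 17 that rose, while Pam fell (-1.06) and 8 did not pass. With quantile normalization 0 fell over all genes, so the call of Pam was lost. The 8 that rose varied together within groups, with a mean residual correlation of 0.832, against a 95th percentile of 0.557 over 10000 random sets of other higher genes, but over all 17 members it was 0.27, against 0.44 for random sets of other tested genes. More atrial tissue in these samples may account for the 8, and WT 3, with a score of 0.95, differed from WT 1 and WT 2 in the same direction, but for the list as a whole the tests leave it open. An effect of genotype on atrial genes stays open and was not tested apart from it.

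Adipocyte markers were called higher as well (adjusted p = 3.44e-10, and adjusted p = 0.326 with an estimated correlation), with 6 of 11 that rose, or 2 of 11 with quantile normalization, while Lipe (0.037), Fabp4 (-0.056) and Cidea (-0.58) were among the 5 that did not pass. The 6 had a mean residual correlation of 0.638, against 0.603 at the 95th percentile, but over all 11 members it was 0.33, against 0.497. More fat tissue in the samples may account for the 6, of which Adipoq had a signal of 54 to 390.7 against 15.7 to 22.3 in WT, but for the list as a whole the tests leave it open. The score was lowest in KO 1 among the libraries labelled KO, as the Esrra difference was, so fat and genotype are not separated by it, and an effect of genotype stays open and was not tested apart from it. Pam, Lipe, Fabp4 and Cidea were singled out after their values were seen.

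The 6 hearts can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 384 genes, the highest of the others 0, and 1 of the 10 splits gave as many as the real one. Every other split puts WT and KO libraries together in both groups. Any difference between WT and KO then enters the spread within groups, so low counts there are in part built in.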

How the results depend on the processing

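The following alternatives were chosen after seeing the data (quantile normalization without KO 1, the atrial and the fat score as covariates, and Esrra in the filtered fit). The cause of the changes given here was not tested, except where fewer hearts or genes were used. Detection calls were not given, so the signal over background that limits dim genes is unknown. Deviations of hearts with equal mouse numbers were hardly correlated (0.027, -0.017 and 0.029), which does not exclude a pairing of small effect. With the replicate block 237 genes were higher and 175 lower.

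Genes higher and lower numbered 48 and 18 without a filter, 114 and 57 without an intensity trend, 434 and 176 with array weights, 514 and 481 without KO 1 and with quantile normalization, 60 and 14 with the atrial score and 15 and 11 with the fat score. Leaving out each heart gave 103 to 299 higher and 19 to 209 lower genes, with 173 and 84 without KO 2, 119 and 77 without KO 3, and 103 and 19 without WT 1, where 84.4% of the calls were higher. Without WT 2 there were 167 and 161. Of the 384 genes, 276 were shared with quantile normalization (260 and 186) and 20 with the fat score.

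Esrra, at -2.58 with an adjusted p of 0.0678, passed the threshold at -2.57 with median centring (0.0188), and at -2.58 with no filter per gene (0.0376), a filter at the 60th percentile (4.06e-46), the mean of probe sets (0.000105), without shared-probe sets (5.52e-08), over every kept probe set (2.4e-07), with the replicate block (0.0234) and in the filtered fit (3.8e-09), and at -3.37 without KO 1 and with quantile normalization (4.89e-05). A limma adjusted p as small as 4.06e-46 from so few arrays rests on variance shared between genes. The Esrra difference ran from -3.39 to -2.12 on leaving out each heart and turned to 0.22 with the fat score. Camera with an estimated correlation called 0 lists and fry 1. The difference of mean array correlations within and between groups, 0.0082, was 0.0053 without a filter, 0.012 at the 60th percentile, 0.0125 without KO 1 and with quantile normalization, and 0.00688 to 0.0125 on leaving out each heart.

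The odds ratio near Esrra at an adjusted p under 0.05 (0.835) turned above 1 with median centring (1.05), without shared-probe sets (1.43), without KO 1 and with quantile normalization (1.12), with the atrial score (2.75), the fat score (2.55) and 200 genes on each side (1.45), and ran from 0.521 to 1.19 on leaving out each heart. At an unadjusted p under 0.05 (0.904) it turned with median centring (1.09), the 60th percentile (1.13), without shared-probe sets (1.01), robust eBayes (1.02), 200 genes (1.1) and the atrial score (1), and ran from 0.806 to 1.11. None of these passed Fisher's exact test.

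Directions of lists by camera turned as follows, with the median log2 difference. Glycolysis turned with no pseudocount (-0.055), median centring (-0.040), no filter (-0.055), without shared-probe sets (-0.11), the replicate block (-0.055) and the fat score (-0.033), and lay between -0.103 and 0.042 on leaving out each heart. Ion channels turned with quantile normalization (0.0026), median centring (-0.025), cyclic loess (0.0018), no filter (-0.019), array weights (0.0031) and the fat score (-0.096), with a range of -0.0998 to 0.040. Angiogenesis and hypoxia turned with quantile normalization (-0.0015), median centring (-0.012), cyclic loess (0.016), the mean of probe sets (-0.039), without shared-probe sets (0.011), every probe set (-0.0037), no intensity trend (-0.026), array weights (0.079), and quantile normalization without KO 1 (0.011), with a range of -0.129 to 0.123. The cytosolic ribosome turned with quantile normalization (0.022), cyclic loess (0.026), quantile normalization without KO 1 (0.0215) and the fat score (0.048). Blood markers turned with every probe set (0.105) and quantile normalization without KO 1 (0.104), with a range of -0.209 to 0.072. Calcium handling turned at the 60th percentile (-0.068), with a range of -0.14 to 0.031, the sarcomere with every probe set (-0.023) and neural markers without shared-probe sets (0.029). On leaving out each heart, lipid storage ranged from -0.145 to 0.022, the interferon response from -0.066 to 0.269, the circadian clock from -0.050 to 0.0135 and leukocyte markers from -0.034 to 0.302.

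With the atrial score, lists of nuclear receptors (0.068), the circadian clock (0.21), immediate early genes (0.0059, adjusted p = 0.839), atrial markers (-0.071, adjusted p = 0.0349, and adjusted p = 0.728 with an estimated correlation) and neural markers (0.074) turned by camera relative to other genes, as did in sign Esrrb (0.037), Xist (0.26), Mybphl (-0.052), Idh3g (0.0001682), Nppa (-0.21), Aplnr (0.024), Tagln (-0.38), Slc4a1 (-0.34), Myl4 (-0.071) and S100b (-0.50). Mybphl and Myl4 are part of the atrial score, as Adipoq and Retn are of the fat score. Their turns, and in part those of the atrial and adipocyte lists, follow from that. With the fat score, which like the Esrra difference is smallest in KO 1 among KO 1 to 3, 12 lists and 39 named genes turned. The lists, besides those given, were ketone and branched chain amino acid use (0.011), sarcomere (0.050), extracellular matrix (-0.0057), interferon response (-0.47, adjusted p = 8.77e-06), circadian clock (0.027), leukocyte (-0.56, adjusted p = 1.05e-09; adjusted p = 0.982 with an estimated correlation for both interferon and leukocyte), adipocyte (-0.24), skeletal muscle (-0.089) and neural markers (-0.32). The genes were Nnt (0.38), Adipoq (-0.24), Scd1 (-0.22), Jchain (-0.13), Myot (0.19), Acad11 (0.025), Cox7a1 (0.13), Uqcrq (0.29), Atp5e (0.10), Atp5c1 (0.033), Pdha1 (0.0034), Idh3a (-0.069), Pfkp (-0.20), Hk1 (-0.019), Acot1 (0.28), Bckdha (0.094), Bcat2 (0.36), Atp1b1 (-0.24), Mfn1 (0.026), Rpl3l (0.22), Rps2 (0.087), Gsta4 (0.038), Igtp (-0.61), Ifi27 (-0.78), Irgm1 (-0.22), Vwf (-0.27), Acta2 (-0.061), Des (0.11), Cd74 (-0.56), Cd52 (-0.78), Lyz2 (-0.19), Slc4a1 (-0.53), Retn (-0.34), Tnni2 (-0.050), Pvalb (-0.19), Atp2a1 (-0.96), Mbp (-0.49), Ncam1 (-0.32) and Scgb1a1 (-1.79). Under other settings Ckmt1 turned with no pseudocount (0.054) and ranged from -0.42 to 0.022 on leaving out each heart, Esrrg (-0.0997) and Atp5c1 (0.037) turned with the mean of probe sets, Uqcrq (0.19), Atp5c1 (0.21), Tfb1m (0.11), Aplnr (0.011) and Hbb-b2 (0.18) without shared-probe sets, and Ppara (-0.23) without KO 1 and with quantile normalization, with a range of -0.25 to 0.36. Of the 15 called lists 4 were called under all 24 settings of the fit, among them hypertrophy and the fetal program, with a median of -0.00442 over every probe set. Endothelial markers gained a call in several settings, among them quantile normalization (0.143, adjusted p = 0.0122). Over lists and settings 696 results kept direction and side of the threshold, 35 lost the call, 23 gained one and 62 turned; over named genes it was 3037, 413, 95 and 60.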

Other observations

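The B1 repeat control probe set, which reads a common repeat in mouse transcripts, had a signal of 1286 ± 181 in WT and 902 ± 39.1 in the libraries labelled KO (SD, n = 3 each) and was not tested. Ucp1, the uncoupling protein of brown fat and a member of the adipocyte list, gave 1, 1.8 and 0.7 in WT and 16.7, 49.5 and 2.7 in KO 1 to 3. Of 508 genes called without the library labelled KO 1, that library lay inside the WT range for 124 (24.4%) and beyond it toward KO 2 and KO 3 for 373.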
